A study of Mus musculus with 7 samples.

How the data were processed

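RNA levels were measured on Affymetrix mouse arrays in OT-I cells, CD8 T cells whose transgenic receptor recognises a peptide of chicken ovalbumin. Per the labels, naive (CD44lo) Ly5.1 OT-I cells were labelled with the dye CFSE, which is diluted at each division, and injected into host mice of 4 kinds. RIP-OVAhi hosts express ovalbumin under the rat insulin promoter and were used as a model of deletional tolerance. OCS/LPS hosts were primed with splenocytes coated with ovalbumin together with lipopolysaccharide. Rag hosts lack T and B cells of their own and drive lymphopenia-induced proliferation. B6 hosts without the antigen gave naive control cells. Cells that had divided at least 2 times (undivided cells for the naive group) were sorted by CFSE level among CD8+ Ly5.1+ cells, 60 h after transfer or, in Rag hosts, after 5 days. Each array held RNA pooled from 10 mice, or from 20 mice in the RIP-OVAhi group. RNA was extracted with Trizol, and 100 ng of total RNA went through 2 rounds of amplification before biotin labelling, per the labels' protocols.

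The deposited table holds log2 expression values of 45101 probe sets on 7 arrays, made with GCRMA per the submitters' processing notes; the GCRMA version is not given in the sources used here. GCRMA corrects the background from the probe sequences, quantile-normalizes and summarises the probes of a set over all arrays together. Quantile normalization gives every array nearly the same distribution, so a change shared by most genes cannot be seen in these values. The deposited values were used as they are, with no further normalization, and no scanner files were analysed here. There is no read depth for arrays; the number of arrays limits the precision.

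Genes were named from the platform annotation: 34958 probe sets had 1 gene symbol, 932 had several and 9211 had none, and only the first kind was named. Of these, 34754 were matched by Entrez identifier to RefSeq genes of GRCm38.p6, 0 symbols changed and 204 kept the symbol of the annotation. The table was used for names and chromosomes only, and no coordinates are given because arrays carry no build of their own. Each of the 18194 genes was represented by its probe set with the highest mean over all arrays, and the 8203 genes with log2 of at least 5 in at least 2 arrays were tested. Values under log2 5 are called near background in the text, and folds against such values are on the GCRMA scale.

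All 7 arrays were fitted in 1 linear model with a mean per group in limma 3.58.1 under R 4.3.3 (lmFit and eBayes). The model had 3 residual degrees of freedom from the 3 groups of 2 arrays, a prior of 2.93 degrees of freedom and a prior SD of 0.156 on the log2 scale. The Rag group has 1 array, which adds no degree of freedom and was assumed to vary like the other groups. For each of the 6 comparisons p-values were two-sided and adjusted by the Benjamini-Hochberg method over the tested genes, and a gene was called at an adjusted p under 0.05. SE is the moderated standard error of the log2 difference. The labels do not say whether the pools of 1 group came from separate experiments, so p-values measure only the spread between these arrays, which may be technical in part. The 2 arrays of each duplicated group differed in sex-linked genes, so they were not repeats of 1 pool. The main fit leaves that difference in the spread.

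For the genes that set RIP-OVAhi apart, calls in the same direction against naive, OCS/LPS and Rag were counted together. Gene lists, 19 of T cell programmes and 10 of other cell types, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 23 lists with at least 3 tested members. Camera asks whether a list moved relative to the other genes. Each list was tested again with an estimated correlation. It was also tested with fry, which asks whether its members moved together in the same direction, without reference to the other genes. Counts of lists called by fry use this test. The mixed form of fry, named where used, allows members to move both ways. Because comparisons share the naive arrays, unchanged groups were simulated against the same controls in 50 draws. The groups, the model, the lists, the thresholds, the rule for named genes and the first set of alternatives were chosen before the data were examined.

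The named genes were, per comparison, the 8 called genes with the largest rise and the 8 with the largest fall whose arrays did not overlap between groups, up to 4 members of each list (called members first, by size), and up to 10 genes per direction of those that set RIP-OVAhi apart. Pdcd1, Bcl2l11, Gzmb, Ifng, Il7r, Cd44, Il2ra and Ccr7 were among the genes to be given in each comparison; 1 further item is not reported here. Il2ra stayed near background on every array and was not tested.

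The procedure was tested on simulated data of 8203 genes with 200 changed genes in each of 20 draws. For RIP-OVAhi against OCS/LPS it recovered 15.1% of the changes of 1.5-fold, 79.8% of those of 2-fold and 99.3% of those of 4-fold, and 5.50% of calls were unchanged genes. For Rag against naive, with its lone array, 52.9% of the 2-fold and 97.5% of the 4-fold changes were recovered. With no gene changed, RIP-OVAhi against OCS/LPS gave 1 called gene and 2 called lists in all 20 draws together. When the 20 tested members of the anergy list were raised by 1 log2 unit, camera called that list in 20 of 20 draws, and 4 other lists in all draws together. Simulated genes were independent of each other, so these draws do not test camera where list members correlate. In the arrays the estimated correlation was 0.473 for the cell cycle list. All simulated arrays of a gene, the lone Rag array included, had the spread estimated by the fit. Real replicate differences had an SD of 0.485 in naive, 0.275 in RIP-OVAhi and 0.281 in OCS/LPS. The shares recovered and the share of unchanged genes among calls therefore hold only where all groups have that spread.

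The alternatives were no filter, a filter of log2 at least 7 in 2 arrays and one of at least 5 in 1 array, the mean of a gene's probe sets, every probe set on its own, quantile normalization of the deposited values, centring each array on its median, eBayes with a trend or robust, a threshold of 0.01, a minimum of 2-fold, a fit of only the 2 groups compared, the replicate number as a block, and leaving out each replicate in turn. Counts without genes of the X and Y chromosomes, and without markers of other cell types and immunoglobulin genes, were added after seeing the data. The 2261 probe sets above the filter with no symbol or several were left out of the comparisons.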

Results

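The data are 7 arrays of sorted OT-I cells in 4 groups: naive cells (n = 2), cells that divided in RIP-OVAhi hosts (n = 2), cells that divided in OCS/LPS hosts (n = 2) and cells that divided in Rag hosts (n = 1). Naive, OCS/LPS and Rag cells came from spleen, and RIP-OVAhi cells from sacral and pancreatic lymph nodes, so tissue and group coincide for RIP-OVAhi. The arrays had medians of 2.97 to 3.08 on the log2 scale, and 33.7% to 34.5% of probe sets lay at log2 5 or more. Across genes, the replicates correlated at r = 0.975 for naive, 0.991 for RIP-OVAhi and 0.991 for OCS/LPS. The naive replicates differed most, with 347 genes more than 2-fold apart against 28 and 31 in the other pairs. The 3' to 5' difference of the Gapdh control probe sets, a measure of RNA integrity and amplification, was 2.59 and 2.43 in naive, 2.08 and 2.03 in RIP-OVAhi, 1.85 and 1.89 in OCS/LPS and 2.21 in Rag.

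Several transcripts of other cell types were present in the spleen arrays and near background in the RIP-OVAhi arrays. The MHC class II gene H2-Aa averaged 6.60 in naive, 6.75 in OCS/LPS, 7.63 in Rag and 2.26 in RIP-OVAhi. Lyz1, a lysozyme gene placed in the myeloid list, lay at 7.40 to 8.67 in the spleen arrays against 2.94 and 3.36 in RIP-OVAhi. Jchain, which joins secreted immunoglobulins, lay at 6.93 to 8.45 in naive and OCS/LPS, at 1.65 and 2.28 in RIP-OVAhi and at 1.65 in Rag. The Rag array alone carried the macrophage genes Csf1r (8.51) and C1qb (7.42) and the red cell gene Alas2 (6.65) at such levels. The B cell receptor gene Cd79a stayed between 2.14 and 2.24 on every array, whereas Ighm read 11.8 to 12.6 on every array, Rag included. The pancreas lists had no member at log2 5 or more on any array; their highest value was 4.80. Of the 10 neutrophil, 5 NK cell, 7 CD4 and regulatory T cell and 12 stromal genes named on the array, 1 each was tested, so these lists had no list test. Il2ra, the receptor chain used to mark activated T cells, averaged 2.61 in naive, 2.55 in RIP-OVAhi, 2.56 in OCS/LPS and 2.55 in Rag. Ikzf2, from the regulatory T cell list, lay at 12.09 and 12.28 in RIP-OVAhi, 9.86 and 10.32 in OCS/LPS, 8.59 and 8.52 in naive and 6.57 in Rag. Sex-linked genes split the arrays by replicate number: Xist lay at 2.67 to 2.74 on the 4 arrays numbered 1 and at 12.7 to 13.0 on the 3 numbered 2, and Kdm5d at 8.63 to 8.82 and 2.57 to 2.64. The Y-linked gene Eif2s3y lay at 11.6 to 11.8 on the arrays numbered 1 and at 4.69 in naive, 3.87 in RIP-OVAhi and 5.85 in OCS/LPS on those numbered 2, the last above log2 5.

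**Figure D1:**
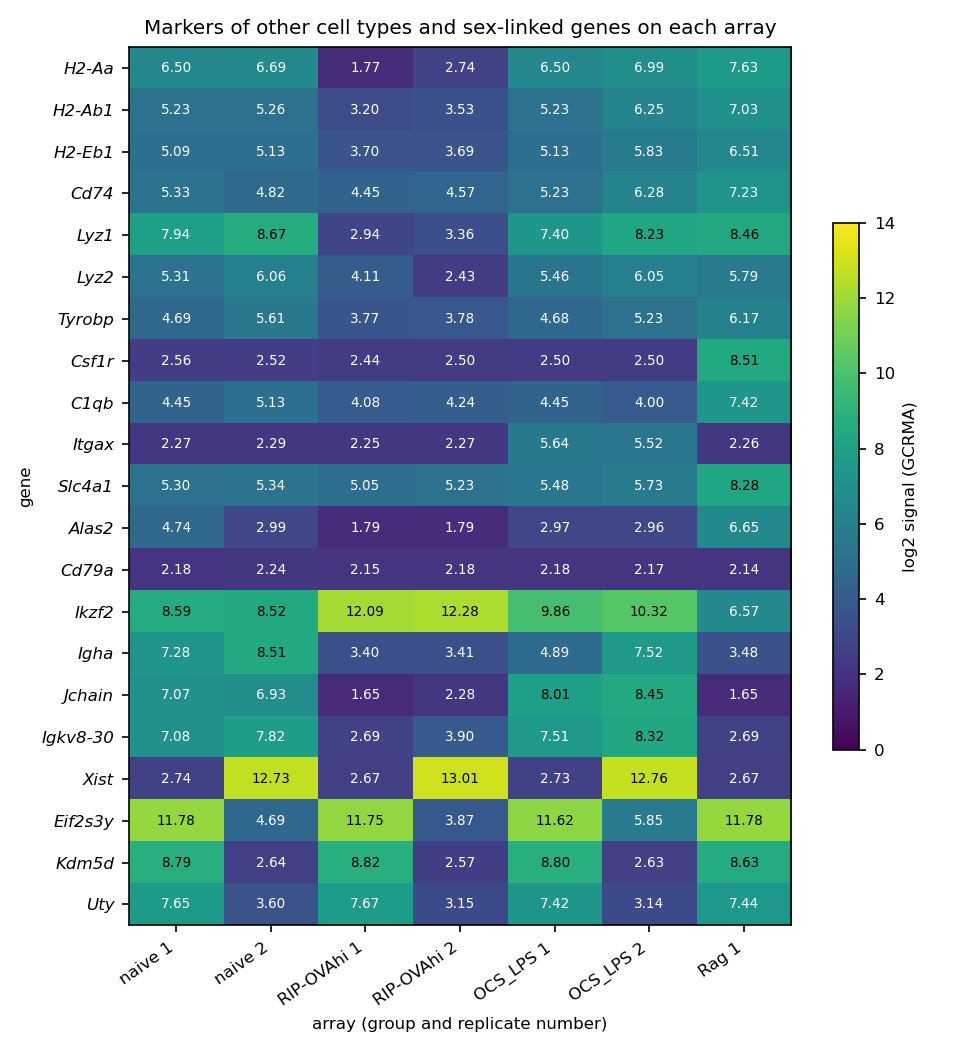
Log2 GCRMA signal of markers of other cell types and of sex-linked genes (vertical) on each of the 7 arrays (horizontal), with the value printed in each cell. Lyz1 is at most 3.36 on the RIP-OVAhi arrays and at least 7.40 on every spleen array, and Xist separates the arrays numbered 1 from those numbered 2.

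The comparison of RIP-OVAhi with naive cells addresses what cells undergoing deletional tolerance express after 60 h. Ctla4, an inhibitory receptor of activated T cells, rose by 7.67 on the log2 scale (SE 0.20, adjusted p = 2.5e-05, n = 2 per group), from 2.47 to 10.13. Pdcd1, which encodes the inhibitory receptor PD-1, rose by 4.20 (SE 0.15, adjusted p = 4.23e-05), and the costimulatory ligand gene Cd86 by 4.14 (SE 0.12). Tnfsf11, which encodes the ligand of the receptor RANK, rose by 6.49 (SE 0.32, adjusted p = 0.000103). Il7r, the receptor for the survival cytokine interleukin-7, fell by 3.36 (SE 0.17, adjusted p = 0.000102), and the granule protease gene Gzma fell by 4.55 (SE 0.17, adjusted p = 4.38e-05) to near background. The largest rises also held the mitotic genes Ccnb2 (6.99), Cenpf (6.78), Aspm (6.77), Bub1 (6.75) and Tpx2 (6.68). Naive values of all these risen genes lay near background, so the sizes and order of such rises depend on the background level. The near-identical heat shock genes Hspa1b (8.09, SE 1.03) and Hspa1a (8.03, SE 1.26) had the largest estimates and the largest errors. The largest falls were Lyz1 (-5.15), Jchain (-5.04), Igfbp4 (-5.02), Gzma, Igha (-4.49), H2-Aa (-4.34), Igkv8-30 (-4.16) and App (-4.10), 5 of them genes of other cell types or immunoglobulins; all but Igfbp4 ended near background.

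All 43 tested cell cycle genes rose, with a median of 4.59, and all 43 when adjusted over the list alone (camera adjusted p = 9.18e-28; adjusted p = 0.319 with an estimated correlation). Of the 21 naive and quiescence genes, 14 fell and 2 rose, or 15 and 3 when adjusted over the list alone (camera adjusted p = 1.08e-05; adjusted p = 0.290 with an estimated correlation). The falls included Bcl2 (-1.74, SE 0.22), an inhibitor of apoptosis, and Cnr2 (-1.57, SE 0.18). Of 9 inhibitory receptor genes, 5 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.00472; adjusted p = 0.319 with an estimated correlation). Among them were Cd200 at 4.63 (SE 0.25) and Lag3 at 3.41 (SE 0.24). The list of genes associated with anergy, a state of unresponsive T cells, had 12 of 20 members higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.000497; adjusted p = 0.319 with an estimated correlation). Its members included the transcription factor genes Irf4 (5.81, SE 0.27), Nr4a2 (3.46, SE 0.17) and Nr4a3 (2.38, SE 0.21) and the folate receptor family gene Izumo1r (5.26, SE 0.12). Of 9 costimulatory genes 6 rose and 0 fell, also over the list alone (camera adjusted p = 0.00516; adjusted p = 0.319 with an estimated correlation). One of them was Tnfrsf9 (2.03, SE 0.24).

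Of 20 ribosome biogenesis and Myc genes, 10 fell and 0 rose, or 11 and 0 when adjusted over the list alone (camera adjusted p = 0.000234; adjusted p = 0.438 with an estimated correlation), and Myc itself fell by 1.40 (SE 0.18). Of 24 interferon response genes 6 fell and 2 rose, or 7 and 2 over the list alone (camera adjusted p = 0.0164; adjusted p = 0.438 with an estimated correlation). Among them were Oasl2 at -2.14 (SE 0.15) and Gbp2 at -1.52 (SE 0.16). The 19 cytotoxic genes went both ways, 6 higher and 6 lower (7 and 6 over the list alone): Ifng rose by 4.04 (SE 0.40) and the serpin gene Serpinb6b by 2.58 (SE 0.27), while Gzma fell. Their median (0.39) and mean (0.22) were positive and camera's direction was down (adjusted p = 0.952); without naive replicate 2 the median was under 0.01, so it gives no direction for the list. Cytokine receptor and feedback genes went both ways too, 4 higher and 4 lower of 11 (5 and 4 over the list alone; camera adjusted p = 0.952): Il2rb rose by 2.43 (SE 0.22), Il10ra by 2.32 (SE 0.13), and Socs3 fell by 4.05 (SE 0.42). In the homing list 5 of 14 rose and 2 fell (6 and 4 over the list alone; camera adjusted p = 0.154), with Itgb1 at 5.09 (SE 0.20), Cxcr5 at 4.68 (SE 0.18), Cxcr3 at 3.03 (SE 0.15) and the memory marker gene Cd44 at 3.90 (SE 0.21). Ccr7, a lymph node homing receptor, fell by 1.09 (SE 0.14, adjusted p = 0.00353). The remaining programme lists had no camera call. Higher and lower members numbered 7 and 1 of 15 for glycolysis, 2 and 0 of 24 for oxidative phosphorylation, 3 and 0 of 15 for cholesterol synthesis, and 4 and 3 of 15 for endoplasmic reticulum stress. They were 2 and 1 of 12 for immediate early genes, whose median (-0.05, or up to 0.04 without 1 array) and mean (0.25) differed in sign, 2 and 1 of 15 for pro-apoptotic genes, 1 and 3 of 11 for survival genes, 3 and 0 of 9 for death receptors and 2 and 0 of 15 for the T cell receptor complex. Over the lists alone these pairs were 7 and 1, 0 and 0, 3 and 0, 8 and 4, 3 and 2, 2 and 1, 1 and 3, 3 and 0, and 1 and 0. Bcl2l11, which encodes the pro-apoptotic protein Bim, rose by 1.28 (SE 0.18, adjusted p = 0.005), Apaf1 rose by 1.67 (SE 0.15) and Bbc3, which encodes Puma, went from 6.91 to 4.91, near background (SE 0.15).

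Beside these, 3 of 5 MHC class II genes and 3 of 5 myeloid genes fell, also over each list alone, with camera adjusted p = 0.0242 and 0.0164 (adjusted p = 0.438 and 0.418 with an estimated correlation), and 1 of 4 B cell genes rose (Cd22, 2.96, SE 0.25) and 1 of 3 erythroid and platelet genes fell. In all, limma called 1481 genes higher and 948 lower (61.0% higher), of which 707 and 390 changed at least 2-fold. Centring each array on its median moved the log2 changes of all genes by -0.12, after which 1192 were higher and 1296 lower (47.9% higher), so smaller changes are relative to that shift; no camera call reversed. Camera called 9 of 23 lists and fry 14; with an estimated correlation camera called 0, and 2 at an unadjusted p under 0.05. The number of genes was 876 and 794 without RIP-OVAhi replicate 1 or 2 and 1598 and 1596 without OCS/LPS replicate 1 or 2. Without RIP-OVAhi replicate 1 or 2 the calls of Gzmb (-2.20, SE 0.43; highest adjusted p = 0.108), Igha (0.0965) and Bcl2l11 (0.0529) were lost, and without replicate 2 that of Hspa1a (0.0687). Among lists, MHC class II lost its call without either naive array (adjusted p = 0.00596 to 0.153 over the arrays left out), the interferon list without naive or RIP-OVAhi replicate 1 (up to 0.0696) and the myeloid list without naive replicate 2 (up to 0.0712).

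The comparison of OCS/LPS with naive cells addresses priming, with both groups taken from spleen after 60 h. Ctla4 rose by 7.62 on the log2 scale to 10.08 (SE 0.20, adjusted p = 1.47e-05, n = 2 per group), Pdcd1 by 3.28 (SE 0.15, adjusted p = 6.07e-05) and Ifng, which encodes the cytokine interferon-gamma, by 4.40 (SE 0.40, adjusted p = 0.000812). Gzmb rose 13.8-fold (log2 3.79, SE 0.43, adjusted p = 0.0019), and the NK cell receptor genes Klrc1 (4.49, SE 0.40) and Klrk1 (4.19, SE 0.22) rose with it. The gut homing receptor gene Ccr9 fell by 6.65 (SE 0.56, adjusted p = 0.000609), followed by Cxxc5 (-5.24), Abca1 (-4.63), Igfbp4 (-4.57), Oasl2 (-4.41), App (-4.13) and Xkrx (-3.93). The largest rises besides Ctla4 were mitotic genes, Aspm (7.53), Nusap1 (7.46), Ccnb2 (7.44), Cenpf (7.36), Tpx2 (7.33), Bub1 (7.31) and Nuf2 (7.12). Naive values of Ctla4, Pdcd1, Ifng, Klrk1 and these mitotic genes, and OCS/LPS values of the named falls except Igfbp4, lay near background, on which the sizes and order of such changes depend.

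All 43 cell cycle genes rose, with a median of 5.01 and also over the list alone (camera adjusted p = 1.49e-26; adjusted p = 0.294 with an estimated correlation). Of 21 naive and quiescence genes 15 fell and 0 rose, also over the list alone (camera adjusted p = 1.91e-06; adjusted p = 0.242 with an estimated correlation). Among them were Bcl2 at -2.75 (SE 0.22), Il7r at -2.38 (SE 0.17, adjusted p = 0.000296) and Cnr2 at -1.86 (SE 0.18). Interferon response genes fell in 13 of 24 cases and rose in 1, or 13 and 2 over the list alone (camera adjusted p = 1.99e-06; adjusted p = 0.294 with an estimated correlation). They included Oasl2 (SE 0.15), Ifit1 (-3.03, SE 0.25) and Ifit3 (-2.39, SE 0.21). Cholesterol synthesis genes rose in 9 of 15 cases, 10 over the list alone, and none fell (camera adjusted p = 0.00182; adjusted p = 0.294 with an estimated correlation). Among them were Cyp51 at 1.76 (SE 0.12), Idi1 at 1.74 (SE 0.19) and Pmvk at 1.69 (SE 0.15). Of 9 inhibitory receptor genes 6 rose and 1 fell, or 7 and 1 over the list alone (camera adjusted p = 0.0136; adjusted p = 0.294 with an estimated correlation). Glycolysis genes rose in 8 of 15 cases and fell in 1, or 9 and 1 over the list alone (camera adjusted p = 0.0229; adjusted p = 0.319 with an estimated correlation). Among them were Hk2 at 2.22 (SE 0.29) and Pgam1 at 1.01 (SE 0.13). Of 24 oxidative phosphorylation genes 8 rose, also over the list alone (camera adjusted p = 0.0422; adjusted p = 0.597 with an estimated correlation). Their median of 0.40 (0.16 to 0.52 over the arrays left out) was 0.25 after centring, where the call was lost (adjusted p = 0.0520; 0.000517 to 0.447 over the arrays left out). Ribosome biogenesis and Myc genes fell in 5 of 20 cases and rose in 1, also over the list alone (camera adjusted p = 0.0229; adjusted p = 0.571 with an estimated correlation). Among them was Myc at -1.25 (SE 0.18). Of 12 immediate early genes 2 fell, 1 over the list alone (camera adjusted p = 0.0422; adjusted p = 0.532 with an estimated correlation).

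The cytotoxic list had 9 of 19 members higher and 3 lower, also over the list alone, and the costimulatory list 4 of 9 higher, also over the list alone. Both had camera adjusted p = 0.0505, which passed after centring (0.0238 and 0.0398). With an estimated correlation camera gave adjusted p = 0.531 and 0.382. Icos rose by 1.54 (SE 0.14), Cd86 by 2.18 (SE 0.12) and Cd28 by 1.07 (SE 0.12). The anergy list had 4 members higher and 3 lower of 20, also over the list alone (camera adjusted p = 0.839), with Irf4 at 5.70 (SE 0.27), Izumo1r at 2.46 (SE 0.12) and Nt5e at -1.34 (SE 0.18); its median of 0.13 (0.03 to 0.15 over the arrays left out) turned negative after centring. Cytokine receptor genes went both ways, 4 higher and 3 lower of 11 (camera adjusted p = 0.787), with Il2rb at 2.70 (SE 0.22) and Il18rap at 1.81 (SE 0.16), and the median of 0.14 turned negative after centring and ranged from -0.17 to 0.39 over the arrays left out. Homing genes did too, 6 and 4 of 14 (camera adjusted p = 0.482), with Itgb1 at 5.06 (SE 0.20), Cxcr3 at 3.95 (SE 0.15) and Cd44 at 3.27 (SE 0.21, adjusted p = 0.000205). Neither list's counts changed over the list alone. Higher and lower members were 5 and 4 of 15 for endoplasmic reticulum stress, 3 and 1 of 15 for pro-apoptotic, 1 and 3 of 11 for survival, 2 and 0 of 9 for death receptor and 2 and 0 of 15 for T cell receptor genes. Over the lists alone they were 7 and 4, 3 and 1, 1 and 3, 2 and 0, and 2 and 0. Apaf1 rose by 1.92 (SE 0.15) and Bbc3 fell by 2.09 (SE 0.15). Bcl2l11 was not called (-0.04, SE 0.18, adjusted p = 0.9), and another of its probe sets pointed the other way. Ccr7 fell by 0.96 (SE 0.14, adjusted p = 0.0048), a call lost without OCS/LPS replicate 2 (0.0506).

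Beside these, MHC class II genes had 0 of 5 higher and 1 lower, myeloid genes 1 higher of 5 (the dendritic cell integrin gene Itgax, 3.30, SE 0.12), B cell genes 2 higher of 4 (Cd22, 4.56, SE 0.25) and erythroid and platelet genes 1 higher of 3; camera called none of the 4 lists. In all, 1685 genes were higher and 1013 lower (62.5% higher), 807 and 394 of them at least 2-fold. Centring moved all log2 changes by -0.15 and gave 1340 higher and 1461 lower (47.8% higher). Camera called 9 of 23 lists and fry 15; with an estimated correlation camera called 0, and 2 at an unadjusted p under 0.05. The number of genes fell to 1182 and 992 without OCS/LPS replicate 1 or 2. List calls were lost without naive replicate 1 or OCS/LPS replicate 2 for immediate early genes (highest adjusted p = 0.253), without naive or OCS/LPS replicate 1 for oxidative phosphorylation (0.447) and without OCS/LPS replicate 1 for ribosome biogenesis (0.0957).

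The changes against naive ran together in the RIP-OVAhi and OCS/LPS groups across the 8203 genes (r = 0.892, covariance 0.882). Unchanged groups that share the naive arrays gave r = 0.500 and a covariance of 0.0226 in simulation. The simulation gave all arrays of a gene 1 spread. Replicate differences had an SD of 0.485 in naive, 0.275 in RIP-OVAhi and 0.281 in OCS/LPS. The simulated values can therefore understate what the shared naive arrays give. Both comparisons called 1208 genes higher and 657 lower, where independent lists would share 304 and 117, and part of the excess may come from the shared naive arrays. There were 20 genes called in opposite directions. RIP-OVAhi was higher in 12 of them, including Lrig1, Nt5e, Sox4 and A530021J07Rik, and lower in 8, including Gzma, Gzmb, Il18rap and Ccl5. Genes are not independent replicates, so these correlations carry no p.

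**Figure D2:**
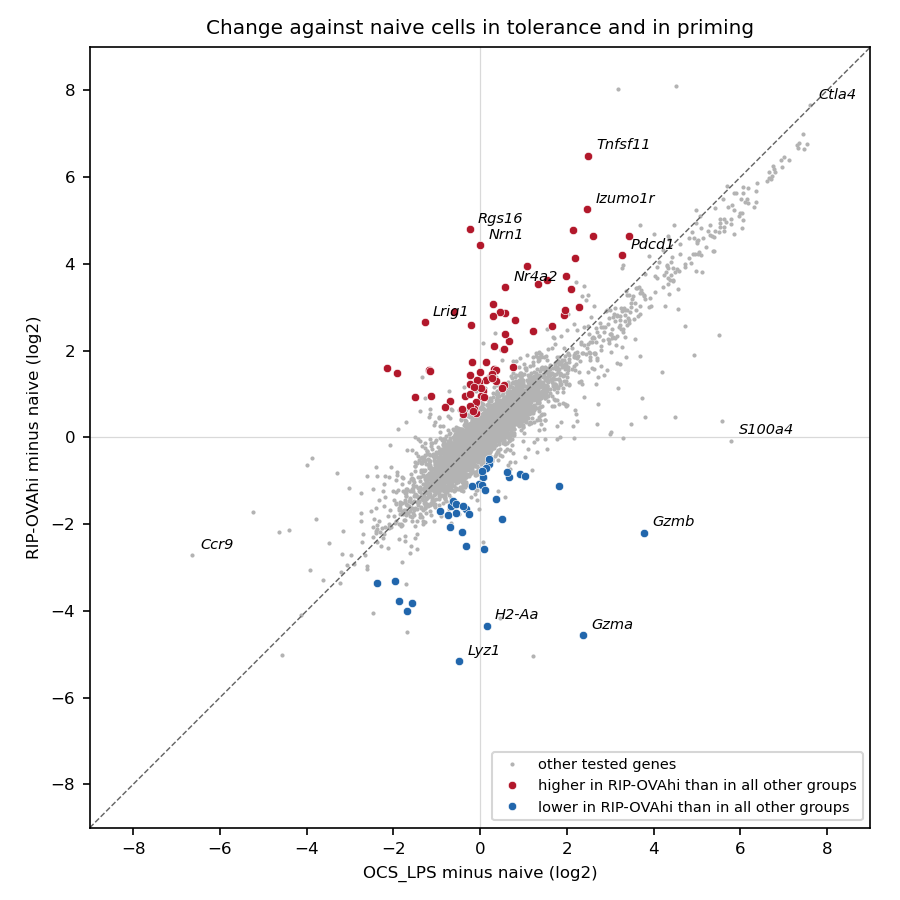
Log2 difference from naive in RIP-OVAhi (vertical) against that in OCS/LPS (horizontal) for the 8203 tested genes, with the line of equal change dashed. Red and blue points are the 72 and 38 genes called higher or lower in RIP-OVAhi than in naive, OCS/LPS and Rag, and r over all genes is 0.892.

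The comparison of RIP-OVAhi with OCS/LPS sets tolerance against priming at the same time after transfer. Gzma was 6.92 lower on the log2 scale in RIP-OVAhi (-6.92, SE 0.17, adjusted p = 6.45e-05, n = 2 per group), at 3.33 ± 0.12 (SD) against 10.26 ± 0.13. Gzmb, the granzyme that activates caspases in target cells, was at 3.31 against 9.30 (-5.99, SE 0.43, adjusted p = 0.00265). The calcium-binding protein genes S100a4 (-5.85, SE 0.14) and S100a6 (-5.20, SE 0.22) were lower too. In the other direction stood Rgs16, a regulator of G protein signalling (5.04, SE 0.22, adjusted p = 0.000371), Nrn1 (4.43, SE 0.20), Tnfsf11 (4.01, SE 0.32), Lrig1 (3.94, SE 0.13), Ccr9 (3.94, SE 0.56), A530021J07Rik (3.73, SE 0.27), Cxxc5 (3.51, SE 0.12) and the chemokine gene Xcl1 (3.48, SE 0.43). The largest falls also held Jchain (-6.26), Lyz1 (-4.67), Igkv8-30 (-4.62) and H2-Aa (-4.49), genes of other cell types or immunoglobulins. Gzma, Gzmb and these 4 genes in RIP-OVAhi, and Rgs16, Nrn1, Ccr9, A530021J07Rik and Cxxc5 in OCS/LPS, lay near background, on which the sizes and order of their differences depend. Ifng did not differ detectably (-0.36, SE 0.40, adjusted p = 0.744).

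**Figure D3:**
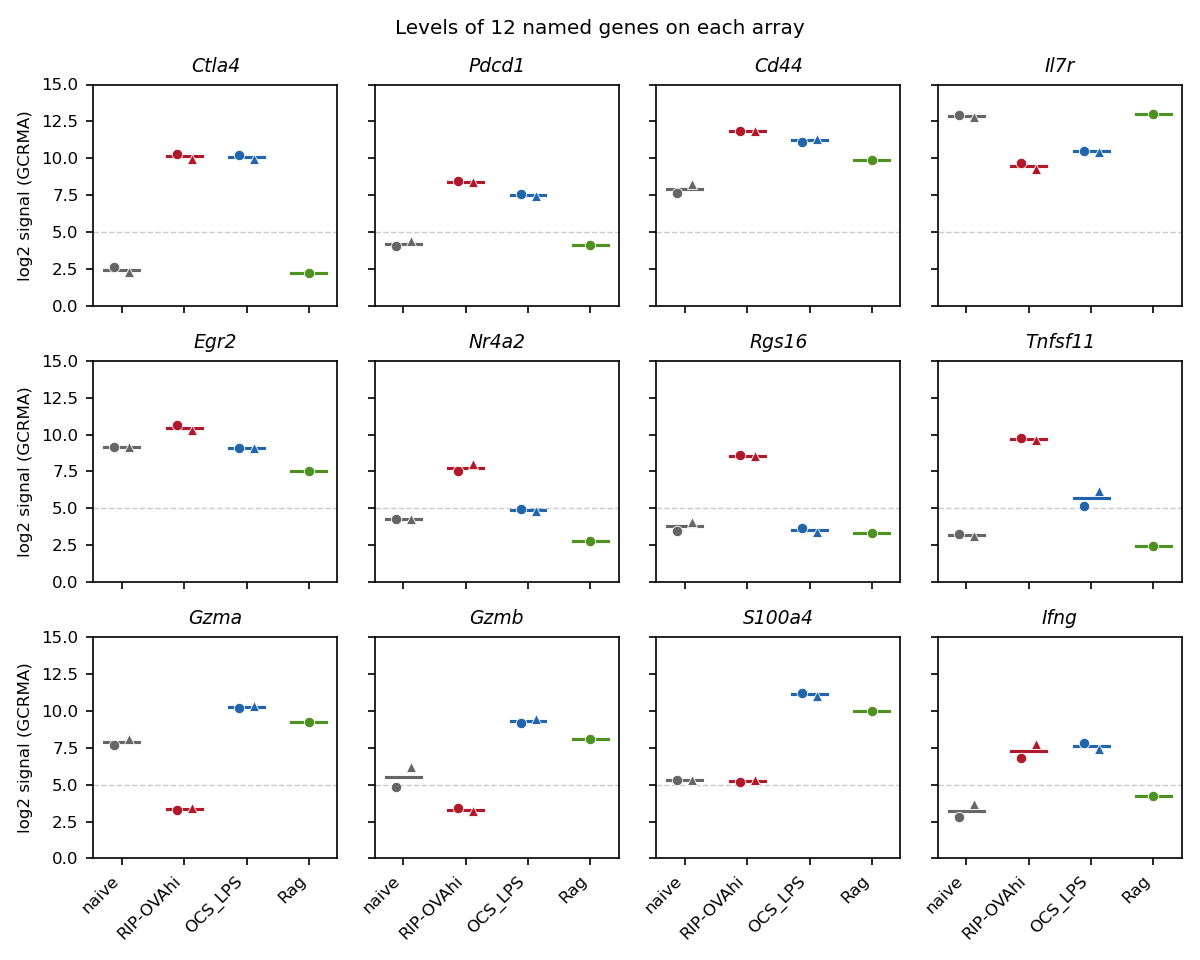
Log2 GCRMA signal of 12 named genes (vertical, 1 panel each) in the 4 groups (horizontal). Points are arrays (circles numbered 1, triangles numbered 2), bars are group means, and the dashed line is log2 5; Gzma averages 3.33 in RIP-OVAhi and 10.26 in OCS/LPS, and Ctla4 averages 10.13 and 10.08.

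The anergy list had 8 of 20 members higher and 1 lower, or 11 and 1 over the list alone (camera adjusted p = 1.59e-10; adjusted p = 0.157 with an estimated correlation). Higher members were Nr4a2 (2.89, SE 0.17), Izumo1r (2.80, SE 0.12), Nt5e (2.72, SE 0.18) and Egr3 (1.99, SE 0.24), and Egr2, a target of calcium signalling linked to anergy, was also higher (1.39, SE 0.16, adjusted p = 0.0129). The stress genes Hspa1a (4.86, SE 1.26, adjusted p = 0.138), Hspa1b (3.57, SE 1.03, adjusted p = 0.169) and Dusp1 (1.53, SE 0.35, adjusted p = 0.101) had positive differences too and were not called. Of 24 interferon response genes 5 were higher and 0 lower, or 8 and 0 over the list alone (camera adjusted p = 7.05e-10; adjusted p = 0.157 with an estimated correlation). They were led by Oasl2 (2.26, SE 0.15) and Ifit1 (1.86, SE 0.25). Cytotoxic genes were lower in 8 of 19 cases and higher in 2, or 11 and 2 over the list alone (camera adjusted p = 4.34e-05; adjusted p = 0.157 with an estimated correlation). Among them were Klrc1 at -4.02 (SE 0.40) among the lower and Xcl1 among the higher. Cholesterol synthesis genes were lower in 2 of 15 cases, Cyp51 (-0.90, SE 0.12) and Insig1 (-0.90, SE 0.14), or 9 over the list alone (camera adjusted p = 2.28e-06; adjusted p = 0.157 with an estimated correlation). Inhibitory receptor genes were higher in 3 of 9 cases and lower in 1, or 4 and 1 over the list alone (camera adjusted p = 0.00962; adjusted p = 0.163 with an estimated correlation). Among them were Cd200 at 2.02 (SE 0.25), Tox at 1.43 (SE 0.23), Pdcd1 at 0.91 (SE 0.15, adjusted p = 0.0387) and Lair1 at -1.92 (SE 0.19). Costimulatory genes were higher in 2 of 9 cases, Cd86 (1.96, SE 0.12) and Tnfrsf9 (1.48, SE 0.24), or 3 over the list alone (camera adjusted p = 0.00201; adjusted p = 0.157 with an estimated correlation). Homing genes were higher in 2 of 14 cases and lower in 1, or 7 and 2 over the list alone (camera adjusted p = 0.00741; adjusted p = 0.157 with an estimated correlation). Among them were Itgae at 2.47 (SE 0.29) and Cxcr3 at -0.92 (SE 0.15).

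The cell cycle list had a median of -0.43 (-0.50 to -0.28 over the arrays left out) with 0 of 43 members called by limma, 0 over the list alone and 14 lower at an unadjusted p under 0.05 (camera adjusted p = 1.66e-06; adjusted p = 0.386 with an estimated correlation; fry mixed adjusted p = 0.0733). Glycolysis (median -0.18, range -0.26 to -0.17), ribosome biogenesis (-0.24, range -0.34 to -0.13 over the arrays left out) and immediate early genes (0.33, range 0.28 to 0.42) were also shifted by camera with 0 members called. Their adjusted p were 0.00748, 0.00553 and 0.0012 (adjusted p = 0.163, 0.386 and 0.221 with an estimated correlation). At an unadjusted p under 0.05 these lists had 3 lower, 4 lower, and 6 higher with 1 lower, and 5 higher and 1 lower immediate early genes passed over that list alone. The immediate early genes Jun (2.11, SE 0.49, adjusted p = 0.105) and Fos (1.78, SE 0.37, adjusted p = 0.0819) were among those not called over all genes. Naive and quiescence genes were lower in 2 of 21 cases (3 higher and 2 lower over the list alone; camera adjusted p = 0.478), Klf3 (-0.98, SE 0.14) and Il7r (-0.98, SE 0.17, adjusted p = 0.0426). Cytokine receptor genes were lower in 2 of 11 cases (2 higher and 3 lower over the list alone; camera adjusted p = 0.538), Il18rap (-2.93, SE 0.16) and Il12rb1 (-1.55, SE 0.12). Bcl2l11 was the 1 pro-apoptotic gene of 15 called, also over the list alone (1.32, SE 0.18, adjusted p = 0.0242; list by camera 0.634), and Il7r the 1 of 11 survival genes (1 higher and 1 lower over the list alone; camera adjusted p = 0.344). By limma 0 members were called among death receptor, oxidative phosphorylation, endoplasmic reticulum stress and T cell receptor genes, against 1, 1, 1 and 2 at an unadjusted p under 0.05, and camera called none of these lists. Cd44 (0.63, SE 0.21, adjusted p = 0.217) and Ccr7 (-0.13, SE 0.14, adjusted p = 0.742) were not called.

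Beside these, 3 of 5 MHC class II, 2 of 5 myeloid and 2 of 4 B cell genes were lower in RIP-OVAhi, with camera adjusted p = 0.00443, 4.24e-05 and 0.00553 (adjusted p = 0.228, 0.157 and 0.157 with an estimated correlation). Over the lists alone 4, 4 and 3 were lower, and 1 MHC class II gene was higher. The B cell genes Cd79a, Pax5 and Ebf1 lay near background on every array and were not tested. Cd22 of the same list averaged 3.82 in naive, 6.78 in RIP-OVAhi and 8.38 in OCS/LPS, so the call of this list need not mark B cells. None of 3 erythroid and platelet genes was called, against 3 lower over the list alone and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0139; adjusted p = 0.163 with an estimated correlation). Itgax, at 5.58 in OCS/LPS and near background elsewhere, was -3.32 (SE 0.12). Klra8, the only tested NK cell gene, lay at 3.23 and 3.38 in RIP-OVAhi and at 4.04 and 5.85 in OCS/LPS and was not called (-1.64, SE 0.62, adjusted p = 0.268). In all, 132 genes were higher and 107 lower, 94 and 79 of them at least 2-fold, and 594 and 763 passed an unadjusted p under 0.05. Camera called 15 of 23 lists and fry 13; with an estimated correlation camera called 0, and 5 at an unadjusted p under 0.05. The number of genes was 21 and 29 without RIP-OVAhi replicate 1 or 2, 26 and 26 without OCS/LPS replicate 1 or 2, and 417 and 418 without naive replicate 1 or 2. The calls of Gzma, S100a4, S100a6, Jchain, Lrig1, Cxxc5, Izumo1r and Il18rap held without any 1 array. Those of Rgs16, Nrn1 and Nr4a2 held without a naive or OCS/LPS array and that of Itgax without a naive or RIP-OVAhi array, but these genes dropped out of the test without an array of the group in which they were present. Other calls were lost without any 1 of RIP-OVAhi replicates 1 and 2 and OCS/LPS replicates 1 and 2. Their highest adjusted p were 0.0708 for Gzmb, 0.0907 for Il12rb1, 0.148 for Igkv8-30, 0.149 for Lair1, 0.157 for Klrc1, 0.200 for Itgae, 0.219 for Cd200, 0.221 for Xcl1, 0.225 for Cyp51 and 0.228 for Ifit1. They were 0.176 for Egr2, 0.258 for Bcl2l11, 0.271 for Tnfrsf9 (lost also without either naive array), 0.288 for Klf3, 0.307 for Il7r, 0.310 for Cxcr3, 0.317 for Insig1, 0.321 for Tox and 0.337 for Pdcd1. Tnfsf11 (0.101) and Ccr9 (0.258) were lost without either RIP-OVAhi array, Cd86 (0.0545) and Nt5e (0.0586) without RIP-OVAhi replicate 1, and H2-Aa (0.0708) and Oasl2 (0.0613) without either OCS/LPS array. Lyz1 (0.0882), A530021J07Rik (0.0693) and Egr3 (0.182) were lost without 3 arrays each: either RIP-OVAhi array or OCS/LPS replicate 2 for Lyz1, either RIP-OVAhi array or OCS/LPS replicate 1 for A530021J07Rik, and RIP-OVAhi replicate 1 or either OCS/LPS array for Egr3. The MHC class II list lost its call without naive replicate 1 or 2 (highest adjusted p = 0.0722) and the ribosome list without OCS/LPS replicate 2 (0.116).

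Genes that set RIP-OVAhi apart from naive, OCS/LPS and Rag cells numbered 72 higher and 38 lower. Independent lists would share 2.34 and 0.853, and part of the excess may come from the shared RIP-OVAhi arrays. Simulated unchanged groups gave 0 of each, but almost no gene is called in such groups, so that result was fixed beforehand. Neither figure shows what groups that differ from naive and Rag would share. Rgs16 (smallest of its 3 log2 differences 4.80), Nrn1 (4.43), Tnfsf11 (4.01), Nr4a2 (2.89), Xcl1 (2.88), Izumo1r (2.80), Gpm6b (2.78), Lrig1 (2.66), Cd83 (2.65) and Phactr2 (2.50) led the higher genes. Among the lower genes, the log2 difference smallest in absolute size was that from naive for Gzma (-4.55), H2-Aa (-4.34), Gzmb (-2.20) and H2-Ab1 (-1.88). It was that from OCS/LPS for Lyz1 (-4.67), the AP-1 gene Fosl2 (-2.31), Cd163l1 (-2.25), Plac8 (-2.17) and Prag1 (-1.90). For Fam71b it was that from Rag (-2.26). Several of these genes lay near background on 1 side, on which the sizes and order of their differences depend. They include Rgs16 and Nrn1 in OCS/LPS, and Tnfsf11, Izumo1r and Cd83 in Rag. In RIP-OVAhi they include Lyz1, Gzma, H2-Aa, Cd163l1, Gzmb and H2-Ab1. Against OCS/LPS, the calls of Gpm6b (highest adjusted p = 0.121), Phactr2 (0.153) and Fosl2 (0.263) were lost without OCS/LPS replicate 1 or 2, that of Prag1 (0.119) without these or RIP-OVAhi replicate 1, and that of H2-Ab1 (0.275) without OCS/LPS replicate 2 or either RIP-OVAhi array. Those of Cd83 (0.242), Fam71b (0.24) and Cd163l1 (0.361) were lost without any 1 of the 4 arrays compared, and that of Plac8 (0.344) without any of these or either naive array. Without 1 array the counts were 2, 6, 10 and 12 higher and 4, 5, 5 and 2 lower when RIP-OVAhi replicate 1 or 2 or OCS/LPS replicate 1 or 2 was left out. They were 108 and 106 higher and 65 and 65 lower without naive replicate 1 or 2. With the replicate number as a block they were 65 and 36, and 57 of the 72 and 32 of the 38 were called in both fits.

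The comparison of Rag with naive cells addresses proliferation driven by lymphopenia, from 1 Rag array taken after 5 days. S100a4 rose 24.7-fold (log2 difference 4.63, SE 0.17, adjusted p = 0.000511, n = 1 and 2), 5830411N06Rik by 4.58 (SE 0.39) and S100a6 by 4.37 (SE 0.27), followed by the cell cycle genes Cenpf (4.37), Nusap1 (4.20), Aspm (4.05) and Ccnb2 (3.83) and by Apol11b (4.05). The T-bet gene Tbx21, a regulator of effector cells, rose by 2.03 (SE 0.16, adjusted p = 0.00311) and Cxcr3 by 2.84 (SE 0.18). The immediate early gene Fos fell by 5.12 (SE 0.46, adjusted p = 0.00566). The largest falls besides were Jchain (-5.35), Igkv8-30 (-4.77), H3f3b (-4.55), Ccr9 (-4.51), Sik1 (-3.97), Hacd1 (-3.72) and Cnn3 (-2.95). Pdcd1 (-0.09, SE 0.18, adjusted p = 0.837), Il7r (0.15, SE 0.20, adjusted p = 0.741), Ifng (1.03, SE 0.49, adjusted p = 0.345), Gzmb (2.59, SE 0.52, adjusted p = 0.0699), Ccr7 (-0.77, SE 0.17, adjusted p = 0.0908) and Bcl2l11 (0.17, SE 0.22, adjusted p = 0.741) were not called, and Cd44 rose by 1.94 (SE 0.25, adjusted p = 0.0197). The 4 cell cycle genes were near background in naive, and Jchain, Igkv8-30, H3f3b, Sik1 and Hacd1 in Rag.

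Of 43 cell cycle genes 23 rose, 33 over the list alone, and none fell (median 2.29; camera adjusted p = 1.47e-23; adjusted p = 0.339 with an estimated correlation). Among them was Mki67 at 3.63 (SE 0.31). Immediate early genes fell in 4 of 12 cases, 8 over the list alone with 1 higher (camera adjusted p = 5.95e-07; adjusted p = 0.339 with an estimated correlation). They included Dusp2 (-1.66, SE 0.16). Anergy genes fell in 4 of 20 cases and rose in 1, or 6 and 1 over the list alone (camera adjusted p = 0.000521; adjusted p = 0.339 with an estimated correlation). Among them was Izumo1r at -1.74 (SE 0.15), near background in both groups. Cytokine receptor genes rose in 3 of 11 cases, 4 over the list alone (camera adjusted p = 0.000473; adjusted p = 0.339 with an estimated correlation), namely Il18rap (2.92, SE 0.20), Il10ra (2.12, SE 0.15) and Il12rb1 (2.01, SE 0.15). Cholesterol synthesis genes had a median of -0.51 (-0.26 without naive replicate 2) with 0 of 15 called by limma, 1 lower over the list alone and 6 lower at an unadjusted p under 0.05 (camera adjusted p = 0.000626; adjusted p = 0.339 with an estimated correlation). The cytotoxic list had 2 higher and 1 lower of 19 (3 and 1 over the list alone; camera adjusted p = 0.266), with Id2 at -2.06 (SE 0.17), and the homing list 2 higher and 1 lower of 14 (2 and 3 over the list alone; camera adjusted p = 0.784). One gene each rose in the interferon (Oas3), costimulatory (Cd86, 1.43, SE 0.14) and survival (Pim1, 2.06, SE 0.24) lists, or 1, 1 and 3 over the lists alone. Camera called none of the 3 lists; for the survival list the adjusted p was 0.0530, and 0.0397 after centring, and it ranged from 0.0217 to 0.414 over the arrays left out. Limma called 0 of 21 naive and quiescence genes (2 higher and 2 lower at an unadjusted p under 0.05), 0 of 9 inhibitory receptor (1 and 2), 0 of 15 pro-apoptotic (2 and 2), 0 of 9 death receptor (2 and 0), 0 of 15 glycolysis (3 and 1), 0 of 24 oxidative phosphorylation (1 and 0), 0 of 20 ribosome (2 and 1), 0 of 15 endoplasmic reticulum stress (1 and 1) and 0 of 15 T cell receptor genes (2 and 0). Median, mean and camera differed in sign for the quiescence, costimulatory, homing, oxidative phosphorylation and endoplasmic reticulum stress lists.

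Beside these, 2 of 3 erythroid and platelet genes rose (Slc4a1, 2.95, SE 0.18, and Car2, 2.25, SE 0.31), 1 of 5 myeloid genes rose (C1qb, 2.63, SE 0.33) and 0 of 5 MHC class II genes were called by limma, with 3 higher over the list alone and 4 at an unadjusted p under 0.05 (camera adjusted p = 0.0530; 0.0174 after centring). With an estimated correlation camera gave adjusted p = 0.575 for the MHC class II list and 0.575 for the survival list. Of 4 B cell genes 0 were called, and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.266). Genes at log2 5 or more only in the lone Rag array could not pass the filter and were not tested. They include Csf1r (8.51 in Rag), Alas2 (6.65) and Adgre1 (5.46). Counts of genes higher in Rag, within the lists and in all, therefore leave such genes out. In all, 176 genes were higher and 48 lower (78.6% higher), 160 and 42 at least 2-fold; after centring 195 and 90 (68.4% higher). Camera called 5 of 23 lists and fry 6; with an estimated correlation camera called 0, and 2 at an unadjusted p under 0.05. The number of genes was 1602 without naive replicate 1, 69 without RIP-OVAhi replicate 1 or 2, and 92 and 91 without OCS/LPS replicate 1 or 2, which enter through the shared spread only. The calls of Cd44 (highest adjusted p = 0.105), Nusap1 (0.114), C1qb (0.0906) and Pim1 (0.0731) were lost without any 1 of RIP-OVAhi replicates 1 and 2 and OCS/LPS replicates 1 and 2, and those of Car2 (0.0817) and Oas3 (0.164) without these or naive replicate 2. Hacd1 (0.0563) and Cd86 (0.0563) were lost without RIP-OVAhi replicate 1 or 2, Ccr9 (0.131) without these or naive replicate 2, and Igkv8-30 (0.0629) without OCS/LPS replicate 1 or 2 or naive replicate 2. The anergy list lost its call without naive replicate 1 (0.0744), and its median of -0.40 ranged from -0.44 to -0.26 over the arrays left out. Gene changes in Rag correlated with those in RIP-OVAhi at r = 0.490 (covariance 0.264) and with those in OCS/LPS at r = 0.576 (covariance 0.332), where the simulation gave 0.406 (0.0225) and 0.4 (0.0221). The simulated values can be too low, because the naive replicates spread more than the simulation assumed. These r alone therefore do not show a shared response. Calls were shared with RIP-OVAhi for 139 higher and 22 lower genes (31.8 and 5.55 for independent lists; 26 opposite) and with OCS/LPS for 147 and 23 (36.2 and 5.93; 15 opposite), and part of the excess may come from the shared naive arrays.

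The comparison of RIP-OVAhi with Rag sets antigen-driven tolerance against lymphopenic division, with time and tissue also different. Ctla4 was higher by 7.87 on the log2 scale (SE 0.25, adjusted p = 0.000157, n = 2 and 1), at 10.13 against 2.26, Tnfsf11 by 7.27 (SE 0.40), Izumo1r at 9.37 against 2.37, Cd83 by 6.44 (SE 0.43), Irf4 by 6.36 (SE 0.33), the neuropilin gene Nrp1 by 6.27 (SE 0.31) and Fos by 6.19 (SE 0.46). Of these all but Fos, and Pdcd1 and Ifng below, were near background in Rag, so the sizes and order depend on the background level. Pdcd1 was higher by 4.29 (SE 0.18, adjusted p = 0.000293), Ifng by 3.02 (SE 0.49, adjusted p = 0.0127), Cd44 by 1.96 (SE 0.25, adjusted p = 0.00629) and Bcl2l11 by 1.11 (SE 0.22, adjusted p = 0.0243). Lower were 5830411N06Rik (-6.52, SE 0.39), Gzma (-5.94, SE 0.21), Cd163l1 (-5.86, SE 0.48), H2-Aa (-5.37), Lyz1 (-5.31), Socs3 (-5.01, SE 0.51), Apol11b (-4.95), Gzmb (-4.79, SE 0.52, adjusted p = 0.00366) and Il7r (-3.52, SE 0.20, adjusted p = 0.000535). Of these only Socs3 and Il7r were above background in RIP-OVAhi. Ccr7 was not called (-0.32, SE 0.17, adjusted p = 0.269).

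Cell cycle genes were higher in 41 of 43 cases, 43 over the list alone (median 2.16; camera adjusted p = 7.28e-24; adjusted p = 0.185 with an estimated correlation). Anergy genes were higher in 12 of 20 cases and lower in 1, also over the list alone, inhibitory receptors in 5 and 1 of 9 (6 and 1 over the list alone), and costimulatory genes in 6 and 0 of 9, also over the list alone. Their camera adjusted p were 4.7e-05, 0.000871 and 0.000276 (adjusted p = 0.185, 0.185 and 0.185 with an estimated correlation). Cholesterol synthesis genes were higher in 6 of 15 cases (10 over the list alone), immediate early genes in 5 of 12 with 1 lower (6 and 1), and homing genes in 4 of 14 with 1 lower (4 and 1). Camera gave adjusted p = 0.000732, 0.00561 and 0.00973 (adjusted p = 0.185, 0.257 and 0.185 with an estimated correlation). Naive and quiescence genes were lower in 11 of 21 cases and higher in 1 (13 and 3 over the list alone), survival genes lower in 3 of 11, also over the list alone, ribosome genes in 5 of 20 (7), interferon genes in 4 of 24 (5) and cytokine receptor genes in 5 of 11 with 2 higher (6 and 2). Camera gave adjusted p = 6.38e-05, 0.00222, 0.000254, 0.0035 and 0.0143 (adjusted p = 0.185, 0.257, 0.257, 0.257 and 0.257 with an estimated correlation). Bcl2 (-2.92, SE 0.26), Pim1 (-2.06, SE 0.24) and Il18rap (-4.04, SE 0.20) were among the lower genes. Without a camera call, cytotoxic genes were 5 higher and 4 lower of 19, pro-apoptotic genes 3 and 1 of 15, death receptor genes 3 and 0 of 9, glycolysis genes 0 and 1 of 15 and endoplasmic reticulum stress genes 2 and 0 of 15. Over the lists alone these were 5 and 4, 3 and 1, 4 and 0, 2 and 2, and 4 and 2. Oxidative phosphorylation and T cell receptor genes had 0 called by limma and 1 and 1 at an unadjusted p under 0.05.

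Beside these, 4 of 5 MHC class II, 3 of 5 myeloid and 2 of 3 erythroid and platelet genes were lower in RIP-OVAhi, with camera adjusted p = 0.00222, 0.00146 and 0.00874 (adjusted p = 0.257, 0.185 and 0.185 with an estimated correlation), and 1 of 4 B cell genes was higher. Klra8, at 6.42 in Rag, was lower (-3.12, SE 0.76, adjusted p = 0.0429), a call lost without RIP-OVAhi replicate 1 or 2 (highest adjusted p = 0.180). Over the lists alone 4, 4 and 2 were lower, and 1 MHC class II gene was higher. In all, 807 genes were higher and 566 lower (58.8% higher), 583 and 336 at least 2-fold. After centring 787 were higher and 701 lower (52.9% higher). Camera called 15 of 23 lists and fry 16; with an estimated correlation camera called 0, and 5 at an unadjusted p under 0.05. The number of genes was 358 and 350 without RIP-OVAhi replicate 1 or 2, 695 and 689 without OCS/LPS replicate 1 or 2, and 2549 and 2557 without naive replicate 1 or 2. The call of Cd44 was lost without RIP-OVAhi replicate 1 or 2 (highest adjusted p = 0.0599), that of Ifng without RIP-OVAhi replicate 2 (0.0711) and that of Bcl2l11 without any 1 of RIP-OVAhi and OCS/LPS replicates 1 and 2 (0.129).

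The comparison of OCS/LPS with Rag, both from spleen, sets priming after 60 h against lymphopenic division after 5 days. Ctla4 was higher by 7.82 on the log2 scale in OCS/LPS, at 10.08 against 2.26 (SE 0.25, adjusted p = 0.000179, n = 2 and 1), Irf4 by 6.26 (SE 0.33), Nrp1 by 6.02 (SE 0.31), Parpbp by 5.18 (SE 0.21), the repressor gene Zbtb32 by 5.17 (SE 0.57), Itgb1 by 5.00 (SE 0.24) and Pdcd1 by 3.37 (SE 0.18, adjusted p = 0.000432). Jchain (6.58) and Igkv8-30 (5.23) were higher as well. Of these genes all but Itgb1 were near background in Rag, as were Klrk1 and Ifng, so the sizes and order depend on the background level. Klrk1 (4.20, SE 0.26), Serpinb6b (3.24, SE 0.33) and Ifng (3.38, SE 0.49, adjusted p = 0.00928) were higher, whereas Gzmb was not called (1.20, SE 0.52, adjusted p = 0.171). Lower were 5830411N06Rik (-6.52), the cholesterol exporter gene Abca1 (-5.85), Oasl2 (-4.60), Igfbp4 (-4.13), Cxxc5 (-4.07), Apol11b (-3.98), Bcl2 (-3.92), App (-3.91) and Il7r (-2.54, SE 0.20, adjusted p = 0.00135), where 5830411N06Rik, Abca1, Oasl2, Cxxc5 and App were near background in OCS/LPS. Cd44 was higher by 1.33 (SE 0.25, adjusted p = 0.0214), and Ccr7 (-0.19, SE 0.17, adjusted p = 0.492) and Bcl2l11 (-0.20, SE 0.22, adjusted p = 0.580) were not called.

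All 43 cell cycle genes were higher, also over the list alone (median 2.60; camera adjusted p = 3.08e-25; adjusted p = 0.228 with an estimated correlation). Cholesterol synthesis genes were higher in 12 of 15 cases, 13 over the list alone (camera adjusted p = 8.73e-07; adjusted p = 0.149 with an estimated correlation). Among them were Cyp51 at 1.96 (SE 0.14) and Idi1 at 1.97 (SE 0.23). Cytotoxic genes were higher in 8 of 19 cases and lower in 1 (8 and 2 over the list alone), inhibitory receptors higher in 4 of 9 (4), costimulatory genes in 4 of 9 (6), anergy genes in 7 of 20 with 1 lower (8 and 1) and glycolysis genes in 5 of 15 with 1 lower (8 and 1). Camera gave adjusted p = 0.0154, 0.00332, 0.0131, 0.0300 and 0.0269 (adjusted p = 0.297, 0.228, 0.228, 0.324 and 0.274 with an estimated correlation). Interferon genes were lower in 12 of 24 cases (16 over the list alone), naive and quiescence genes in 10 of 21 (11, with 1 higher), survival genes in 4 of 11 (6), cytokine receptor genes in 4 of 11 with 1 higher (7 and 1) and ribosome genes in 1 of 20 (0). Camera gave adjusted p = 2e-08, 6.74e-06, 0.000493, 0.0154 and 0.0154 (adjusted p = 0.228, 0.149, 0.255, 0.297 and 0.445 with an estimated correlation). Oxidative phosphorylation genes were shifted up (median 0.37) with 0 of 24 called by limma and 5 higher at an unadjusted p under 0.05 (camera adjusted p = 0.0154; adjusted p = 0.445 with an estimated correlation). Without a camera call, higher and lower genes were 4 and 1 of 14 for homing, 5 and 0 of 12 for immediate early, 2 and 1 of 15 for endoplasmic reticulum stress, 3 and 1 of 15 for pro-apoptotic, 1 and 0 of 9 for death receptor and 1 and 0 of 15 for T cell receptor genes. Over the lists alone these were 5 and 2, 5 and 0, 4 and 2, 3 and 1, 1 and 0, and 0 and 0.

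Beside these, 2 of 4 B cell genes were higher (4 over the list alone), and 0 of 5 MHC class II genes were called by limma, with 3 lower over the list alone and 3 at an unadjusted p under 0.05. These lists had camera adjusted p = 0.0131 and 0.0154 (adjusted p = 0.228 and 0.312 with an estimated correlation). Myeloid genes were 1 higher and 1 lower of 5, and 1 of 3 erythroid and platelet genes was lower. In all, 917 genes were higher and 566 lower (61.8% higher), 617 and 309 at least 2-fold. After centring 825 were higher and 739 lower (52.7% higher). Camera called 15 of 23 lists and fry 15; with an estimated correlation camera called 0, and 4 at an unadjusted p under 0.05. The number of genes was 610 and 606 without RIP-OVAhi replicate 1 or 2, 451 and 373 without OCS/LPS replicate 1 or 2, and 2825 and 2835 without naive replicate 1 or 2. The call of Ifng was lost without OCS/LPS replicate 1 or 2 (highest adjusted p = 0.0704) and that of Cd44 without any 1 of OCS/LPS and RIP-OVAhi replicates 1 and 2 (0.122). List calls were lost without OCS/LPS replicate 1 for the anergy (0.111), cytotoxic (0.0941), oxidative phosphorylation (0.0519) and ribosome (0.0935) lists, the first also without either naive array.

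**Figure D4:**
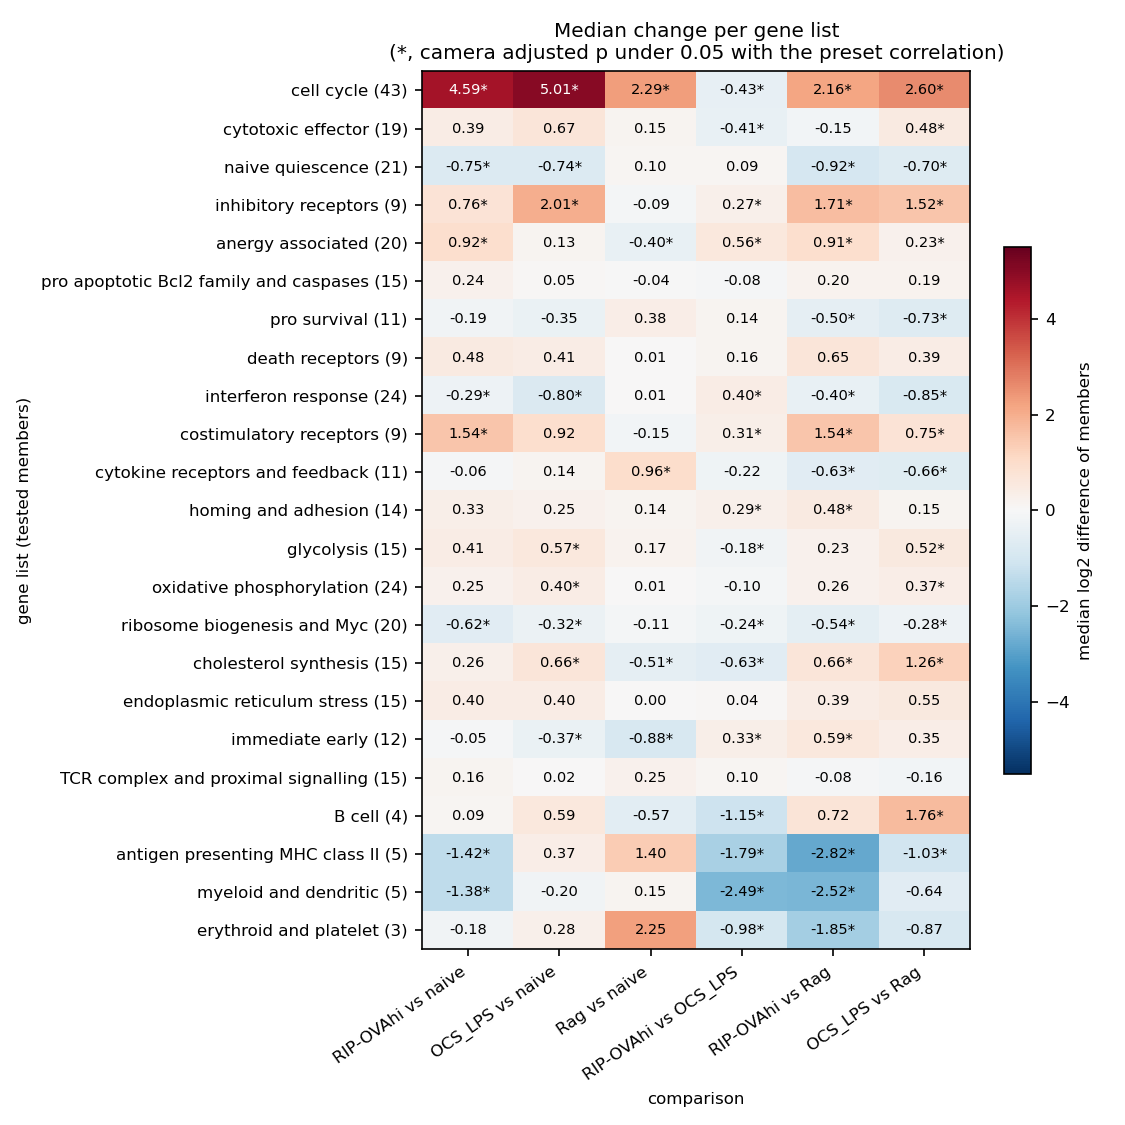
Median log2 difference of each gene list (vertical, tested members in brackets) in the 6 comparisons (horizontal), with the value in each cell and an asterisk where camera with the preset correlation gave an adjusted p under 0.05. With an estimated correlation camera called 0 lists in all 6 comparisons. The cell cycle list has medians of 4.59, 5.01 and 2.29 against naive, and the anergy list 0.92, 0.13 (negative after centring) and -0.40.

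Because the replicate numbers also split the arrays by sex-linked genes, each comparison between the pairs of arrays was made within replicate number 1 and within 2 as well. The 2 sets of differences correlated across all genes at r = 0.889 for RIP-OVAhi against naive, 0.877 for OCS/LPS against naive and 0.787 for RIP-OVAhi against OCS/LPS. With the replicate number as a block the 6 comparisons gave 2299, 2610, 187, 231, 1043 and 1031 genes, in the order in which the comparisons with naive, RIP-OVAhi against OCS/LPS, and those with Rag are listed. Among the calls given above, the block ended that of Oas3 for Rag against naive (adjusted p = 0.0546). For RIP-OVAhi against OCS/LPS it ended those of Pdcd1 (0.0626), Cd163l1 (0.0626), Cxcr3 (0.0517) and Insig1 (0.0519).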

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

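The tests of explanations below were chosen only after the results were seen, whereas the comparisons they start from were fixed before. A test of the difference between the effects of RIP-OVAhi and OCS/LPS against naive called 239 genes, and 20 of them were called in opposite directions against naive. In 12 of the 20 the RIP-OVAhi effect was higher on the log2 scale: A530021J07Rik (3.73), Sox4 (3.40), Lrig1 (3.94), Cyth3 (2.74), Nt5e (2.72), Basp1 (2.43), Ephx1 (2.09), Prmt2 (1.51), Skil (1.32), Inpp4b (1.28), Ski (1.21) and Nrip1 (0.94). In 8 it was lower: Gzma (-6.92), Jchain (-6.26), Gzmb (-5.99), Il18rap (-2.93), Lair1 (-1.92), Baiap3 (-1.75), Ccl5 (-1.59) and Rnf157 (-1.44). Probe sets that the annotation gives no symbol or several were outside the comparisons; of 2261 such probe sets, 169 were higher in RIP-OVAhi than in naive and 346 lower.

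Several transcripts of other cell types were lower in RIP-OVAhi, the only group from lymph nodes, although H2-DMa and Pecam1 had their highest group means there. Whether RNA of MHC class II and lysozyme expressing host cells carried over from spleen was the source stays open: 7 of 8 markers (8 of 10 when those present in either group are counted) had both RIP-OVAhi arrays below all 4 naive and OCS/LPS arrays, which restates the pattern. Immunoglobulin transcripts from host B-lineage cells could be a further source, since 3 of 3 such genes were under log2 5 in the Rag array, against 35.1% of the other genes with that pattern. The same carried-over cells were also considered as the source of the granzymes of OCS/LPS: Gzma rose from naive by 2.37 and Gzmb by 3.79. The largest rise among markers present in both groups was 0.68, which argues against a larger amount of the cells so marked as the source. Among markers present in either group the largest rise was 3.30, from Itgax, so the test as set did not decide. Itgax was near background in both naive and RIP-OVAhi, and cells marked by it stay open as a source. NK cells as a source of granzymes stay open, although the cells were gated on CD8 and Ly5.1: Klra8, the only tested NK gene, was at 5.08 or less in naive, 3.23 and 3.38 in RIP-OVAhi, 4.04 and 5.85 in OCS/LPS and 6.42 in Rag.

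Egr2, Egr3, Nr4a1, Nr4a2 and Nr4a3 were higher in RIP-OVAhi than in OCS/LPS, by 1.39 to 2.89 with a median of 1.80; without 1 RIP-OVAhi or OCS/LPS array the calls of Egr2 (highest adjusted p = 0.176), Nr4a1 (0.188) and Nr4a3 (0.188) were lost in each case, that of Egr3 (0.182) without 3 of these 4, and that of Nr4a2 held in the fits that tested it (0.0426). Handling stress of the sorted cells could raise them, and the test did not decide: the immediate early list had a median of 0.33, but Jun (2.11, SE 0.49), Dusp1 (1.53, SE 0.35) and the heat shock genes Hspa1a (4.86, SE 1.26) and Hspa1b (3.57, SE 1.03) ran with this explanation, though none was called. Within RIP-OVAhi, Egr2, Egr3, Nr4a1 and Nr4a3 were lower in replicate 2 (-0.38, -0.70, -0.50 and -0.39), where Nr4a2, the largest of the 5 differences, was 0.42 higher, as were Fos (0.89), Jun (1.05), Dusp1 (1.04), Hspa1a (1.76) and Hspa1b (0.89). Tissue of origin could not be separated, with 0 lymph node arrays outside the RIP-OVAhi group. That stimulation in tolerance raises these genes is a hypothesis which these arrays leave open.

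Arrays of 1 replicate number deviated together across groups, with replicate differences correlated over all genes at r = 0.348 for naive with RIP-OVAhi, 0.132 for naive with OCS/LPS and 0.325 for RIP-OVAhi with OCS/LPS. Male cells in the arrays numbered 1 and female cells in those numbered 2 could be a source. Xist, Kdm5d and Uty had the levels of their number on all 7 arrays, and Eif2s3y on 6 of 7. The test as set did not decide, only because OCS/LPS replicate 2, with Xist at 12.8, had Eif2s3y at 5.85, above the cut of log2 5. That value is still far below the 11.6 to 11.8 of the arrays numbered 1. Over the 7931 autosomal genes r fell to -0.0588 for naive with OCS/LPS and -0.0242 for RIP-OVAhi with OCS/LPS. It was 0.196 for naive with RIP-OVAhi, where some correlation remained over autosomal genes. Each such r rests on a single replicate difference per group, over genes that are not independent, and its spread was not estimated. Sex-linked genes as the whole of that pair's shared deviation were therefore not excluded.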

How the results depend on the processing

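No called gene or list named in the report reversed in the alternatives that recomputed it; named genes were not recomputed for every probe set on its own, the fits of 2 groups, the threshold of 0.01 or the minimum of 2-fold. Of 434 called values of named genes, 197 lost their call when 1 array was left out and 237 did not in the fits that tested them; such fits have fewer arrays, and a lone array of a group is assumed to vary like the other groups. Genes near background on these arrays were not tested, which limits what low signal can show. The cause of the shifts below was not tested, except that a stricter threshold on p or fold leaves fewer calls by construction. Fewer arrays gave fewer calls in some fits and more in others, depending on which array was left out. Naive arrays enter RIP-OVAhi against OCS/LPS only through the shared spread, and the naive replicates differed most. Fitted with only its 2 groups, that comparison had 416 calls against 239, and RIP-OVAhi against naive 1601 against 2429. The shared spread can thus make p too large for RIP-OVAhi against OCS/LPS and too small against naive. Comparisons are given in the order RIP-OVAhi against naive, OCS/LPS against naive, Rag against naive, RIP-OVAhi against OCS/LPS, RIP-OVAhi against Rag and OCS/LPS against Rag.

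Leaving out 1 array gave 794 to 3261, 992 to 3625, 69 to 1602, 21 to 418, 350 to 2557 and 373 to 2835 called genes, 2 to 108 higher and 2 to 65 lower genes of RIP-OVAhi alone, and r of 0.883 to 0.902, 0.477 to 0.546 and 0.562 to 0.641 for the effects of RIP-OVAhi and OCS/LPS, RIP-OVAhi and Rag, and OCS/LPS and Rag. Called lists ranged over 7 to 9, 7 to 11, 5 to 6, 14 to 16, 15 to 16 and 11 to 16. An adjusted p under 0.01 left 1097, 1281, 75, 53, 483 and 469 genes, and 19 higher and 5 lower in RIP-OVAhi alone. At least 2-fold left 1097 and 1201 against naive, 926 for OCS/LPS against Rag, and 45 and 23 in RIP-OVAhi alone. Every probe set on its own gave 4361, 5207, 2280 (RIP-OVAhi against Rag) and 2630 (OCS/LPS against Rag) probe sets and r of 0.883, 0.460 and 0.513. Only the 2 groups compared gave 1601, 0 (Rag against naive), 416 (RIP-OVAhi against OCS/LPS), 0 (RIP-OVAhi against Rag) and 0 (OCS/LPS against Rag) genes by limma, where the 3 counts of 0 had 1 residual degree of freedom and 543, 3318 and 3312 genes at an unadjusted p under 0.05. Without a filter RIP-OVAhi against OCS/LPS had 105 genes, RIP-OVAhi alone 35 and 15, and Rag against naive 11 called lists, or 9 with log2 of at least 5 in 1 array. With log2 of at least 7, OCS/LPS against naive had 5 called lists and r was 0.902 for RIP-OVAhi and OCS/LPS and 0.520 for RIP-OVAhi and Rag. An estimated correlation in camera left 0 called lists in all 6 comparisons, with 2, 2, 2, 5, 5 and 4 at an unadjusted p under 0.05, and fry called 14 and 15 against naive, 6 for Rag and 13, 16 and 15 for the rest. The replicate block gave r of 0.523 for RIP-OVAhi and Rag and 0.620 for OCS/LPS and Rag and ended 33 calls of named genes. Chosen after seeing the data, leaving out genes of the X and Y chromosomes gave 2357, 2623, 230, 242, 1337 and 1436 genes, and leaving out markers of other cells and immunoglobulin genes 2418, 2700, 218, 226, 1365 and 1480.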

Other observations

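Further genes of the set that was higher in RIP-OVAhi than in naive, OCS/LPS and Rag cells, chosen here after their values were seen, include Tbc1d4 (smallest of the 3 log2 differences 2.23), Rgs1 (2.20), Ikzf2 (2.09) and Cd200 (2.02). Rgs1, like Rgs16, encodes a regulator of G protein signalling, and Ikzf2 encodes the transcription factor Helios. Ikzf2 was 3.63 higher than in naive, 2.09 higher than in OCS/LPS and 5.61 higher than in Rag cells. On the lower side, Cd7 was at -2.17 against naive, -1.75 against OCS/LPS and -2.43 against Rag.

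The near-identical heat shock genes varied within groups: Hspa1a lay at 9.18 and 10.94 in RIP-OVAhi, 7.18 and 3.22 in OCS/LPS and 2.02 and 2.03 in naive. Its difference between RIP-OVAhi and OCS/LPS was 4.86 (SE 1.26) and was not called (adjusted p = 0.138). The hybridization control BioB read 5.14 (5' probe set) and 4.24 (3' probe set) in RIP-OVAhi replicate 1, against 6.14 to 7.02 and 5.81 to 7.26 on the other arrays.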
